A study of Mus musculus with 21 samples.

How the data were processed

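The series holds 21 samples of mouse cells that the labels name LKS SLAM, the marrow fraction enriched for haematopoietic stem cells, in 3 transplantation cohorts. The 10 groups of bulk libraries and the single-cell plate are named by cohort, fluorescent colour and assay in the labels. RNA-seq covered 3 red and 3 yellow libraries in cohort 1 and 2 green and 2 purple libraries in cohort 2. Whole-genome bisulfite sequencing (WGBS) covered 1 red and 1 yellow library in cohort 1 and 2 green and 2 purple libraries in cohort 2. The 4 ATAC-seq samples were not analysed here.

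The RNA-seq files hold whole-number read counts per gene symbol as deposited, not normalized, with closing lines for reads given to no gene. Those lines held 27.0 to 36.1% of each file's total in cohort 1 and 33.3 to 35.8% in cohort 2, and they stayed out of library sizes and tests. TopHat2, HTSeq, BSMAP 2.7, Bowtie2 and the mouse build mm9 are named in the submitters' processing notes without a role or order, and the annotation is not given in the sources used here. Strand use in the counting is not given either, so reads of a gene and of its antisense partner cannot be told apart. The WGBS files list, per covered CpG, the methylated reads over all reads as text, and a deposited score equal to 1000 times that share, which was used only to check the read numbers. Whether both strands were merged is not stated, and no 2 listed positions lay 1 bp apart. The single-cell file holds a deposited count of reads for 23420 genes in 384 wells, made with Smart-seq2 and Nextera XT per the labels' extract protocol, with no molecular identifiers described. The deposited readme assigns wells to 3 clonal clusters by plate position and names 2 wells as empty.

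Counts were tested with edgeR 4.0.16 (R 4.3.3), each cohort on its own, with TMM normalization, the default filter on low counts and the quasi-likelihood test on group means. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Fold changes are log2 of red over yellow and of green over purple, and their SE is the fold change divided by the square root of the F statistic. The labels do not say that the libraries of a colour came from separate animals, so p-values measure the spread between these libraries, which may be technical. No pair of same-colour libraries agreed within sampling noise. Gene lists (32 in all, from stem cell programmes to markers of other marrow cells) were fixed before the data were examined and tested with camera in limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 4 tested members. Camera with an estimated correlation and fry were the alternatives. DESeq2 1.42.0, RLE size factors, other filters, a replicate block, a lane block, all 10 libraries in 1 fit and leaving out each library were alternatives for the gene tests. DESeq2 gave no adjusted p for 6381 of 8229 genes in cohort 1 and 2711 of 11653 in cohort 2, which stayed without one.

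Genes are named by a rule set in advance. Called genes with non-overlapping replicates and the largest changes come first, and where fewer than 10 pass, the 10 genes of smallest p are named as values. Up to 4 tested members of smallest p are named from each gene list, with Xist and 4 Y-linked genes as identity checks. For methylation, the 5 called tiles with the largest differences in each direction and at least 5 CpGs are named. The rule named 107 genes in cohort 1 and 127 in cohort 2.

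WGBS reads were summed over the CpGs of 1000 bp tiles, so a read that spans several CpGs was counted at each. Read numbers of tiles are these sums. Tiles had at least 3 covered CpGs and 20 reads in every library compared. For cohort 2 a quasi-binomial model of methylated and unmethylated reads was fitted per tile, with the dispersion moderated by limma and not below 1. The moderation gave every tile the same dispersion, 1.249. The spread between a tile's own replicates therefore did not enter its p, which measures read sampling scaled by that value. That p takes counts of the same read at neighbouring CpGs as independent, so it can overstate the evidence. Tiles were called at an adjusted p under 0.05 and a difference of at least 20 percentage points. Cohort 1 has 1 library per colour and no test, so tiles that differed by at least 40 percentage points were counted. Coordinates are those of the files, 1-based. No mm9 annotation was used here, so tiles were not assigned to genes, and promoter methylation was not set against expression.

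Wells with at least 500 detected genes were kept. Counts were scaled to 10000 per well, and 2000 variable genes, 20 principal components and 15 neighbours entered Leiden clustering at resolution 1 (scanpy 1.11.5, igraph 0.11.9). A cluster was named from markers fixed in advance if at least 3 of them were raised at least 2-fold and seen in at least 25% of its wells. It also needed more of them than of any other type and 1 of them among its top 10 genes by fold. The last condition was added after the first clustering had been seen. No doublet caller was run, since each well was sorted as a single cell. Shares of wells were compared after thinning each well to 20000 reads and carry exact (Clopper-Pearson) 95% binomial intervals. These intervals cover counting error only. The plate is 1 sample, so no test was made between clonal clusters, and genes were named by the size of the difference in share between clusters 2 and 3, 10 in each direction.

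Scripts ran on Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were checked on simulated data. For cohort 1 (8229 genes), edgeR recovered 19.4, 73.1 and 87.9% of genes changed by 1, 2 and 3 on the log2 scale, with 2 false calls. For cohort 2 (11653 genes), it recovered 14.9, 68.7 and 72.7%, with 5 false calls. A gene list raised by 0.7 was called by camera in both cohorts, with 0 of 25 and 0 of 31 other lists. That absence of false calls need not hold for lists whose genes move together in the real libraries. The immediate early genes of cohort 2 had an estimated correlation of 0.786. In cohort 1 the split of red 1, yellow 1 and yellow 3 from the other libraries called 6 lists. The simulation therefore does not settle whether the preset correlation was high enough. The tile model (1716947 tiles) recovered 16.2, 50.2, 81.8 and 95.2% of tiles changed by 20, 30, 40 and 50 percentage points. It made 35 false calls among 1252. That simulation gave all tiles 1 shared dispersion, as the model assumes, so its share of false calls need not hold for real tiles. In cohort 2, splits that mixed the colours called 69 and 73 tiles against 79 in the real split. In the test of single-cell variability, 100 genes given 8-fold reads in 20% of wells reached the percentile 100.0, and 21.0 when untouched.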

Results

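Haematopoietic stem cells were followed by colour in mice carrying HUe, a transgene whose cassette of fluorescent proteins is recombined by Cre so that a cell and its descendants share a colour. Donor marrow was induced through Mx1-Cre, pooled, sorted and transplanted into irradiated recipients. After 16 weeks LKS SLAM cells of different colours, which stand for different clonal clusters, were sorted for sequencing. The sort used a lineage cocktail against mature blood cells together with cKit, Sca, CD48 and CD150. In cohort 1 the 6 RNA-seq libraries held 3800874 to 5328482 reads in genes, of which the ribosomal RNA precursor Rn45s took 75.4 to 80.3%. In cohort 2 the 4 libraries held 5547820 to 7496030, with at most 1.03% in Rn45s. The 6 WGBS libraries held 84787830 to 193192049 reads at CpGs, a mean of 4.25 to 9.20 per covered CpG. The single-cell plate held a median of 67475 reads per well.

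The comparison of red with yellow cells in cohort 1 asks which transcripts differ between clonal clusters of the same cohort. Histone genes, whose products package DNA, were higher in the red libraries. Vwf, which encodes the clotting protein von Willebrand factor and marks platelet-biased stem cells, was higher in the yellow ones. Hist1h2ak stood at 490 ± 139 CPM (counts scaled to the TMM-adjusted library size) in red and 225 ± 20.3 in yellow (mean ± SD, n = 3 each), a log2 difference of 1.12 ± 0.21 (SE). Vwf stood at 18.1 ± 1.08 CPM in red and 42.7 ± 7.55 in yellow, a log2 difference of -1.24 ± 0.27. Imprinted genes were also higher in yellow as a list, and genes of ribosomal proteins and of oxidative phosphorylation were higher in red. None of the 6 lists called by camera stayed called with an estimated correlation between genes, with an adjusted p = 0.277 to 0.479 with an estimated correlation.

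No single gene passed the threshold between red and yellow. Of 8229 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 432 at an unadjusted p under 0.05 (244 higher in red, 188 in yellow). DESeq2 called 4, with 457 at an unadjusted p under 0.05. The 4 were Hist1h2ak (adjusted p = 0.0856 in edgeR), Hist1h2bn (0.246) and Hist1h2bm (0.416), all higher in red, and Vwf (0.246), higher in yellow. Among the 10 genes of smallest p were also Hist1h2ab, Hist1h2bj and Hist1h2ai, with log2 differences of 1.07 ± 0.26, 1.13 ± 0.28 and 0.92 ± 0.25. Psmd6, a subunit of the proteasome lid, stood at 15.6 ± 1.44 CPM in red and 4.31 ± 2.48 in yellow. Mib1, a ubiquitin ligase of Notch ligands, stood at 7.19 ± 0.967 CPM in red and 20.1 ± 3.07 in yellow. Tet3, which oxidises 5-methylcytosine, stood at 38.3 ± 5.20 against 18.6 ± 3.92 CPM. It was the only member of the DNA methylation machinery list with an adjusted p under 0.05 over the list alone (adjusted p = 0.0131, edgeR). Without red 3 the count of called genes was 7, and it was 0 without any other library.

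**Figure D1:**
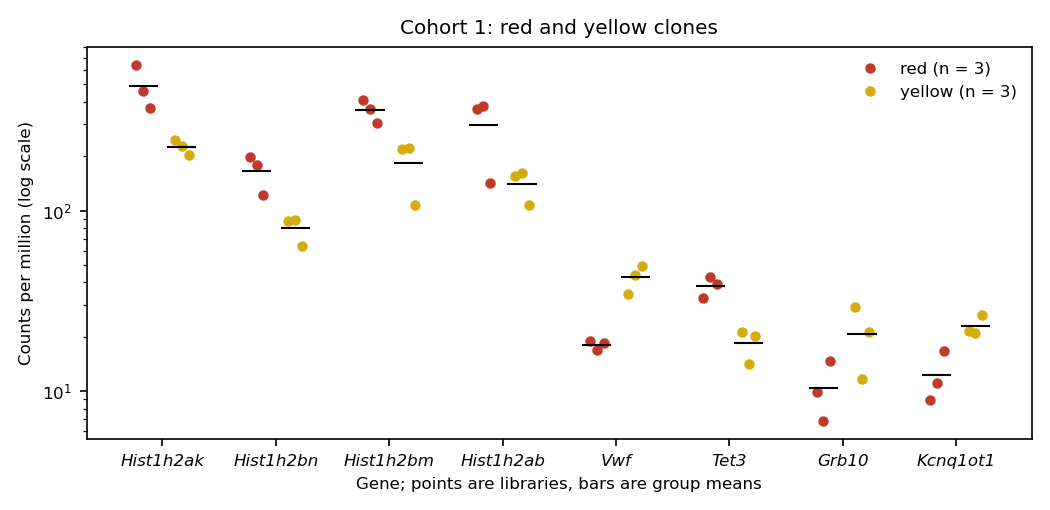
CPM (log axis) of 8 genes in the 3 red and 3 yellow libraries of cohort 1, with points for libraries and bars for group means. Hist1h2ak lay between 368 and 641 in red and between 204 and 245 in yellow, and Vwf between 16.8 and 18.9 in red and between 34.4 and 49.3 in yellow.

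Histone genes made the strongest list. Of 19 tested members 18 were higher in red, with a median log2 difference of 0.65 (camera in limma, adjusted p = 1.01e-13). With an estimated correlation the list had an adjusted p = 0.388. Adjusted over the list alone, 15 members passed, 14 higher in red, such as Hist1h2ab (1.07), Hist1h1e (0.73 ± 0.21), Hist1h2bc (0.75 ± 0.24) and Hist2h2ac (0.75 ± 0.24), and 1 higher in yellow, the linker histone H1f0 (-0.70 ± 0.27). Over all genes tested, 0 passed in edgeR. RNAs without a poly(A) tail were higher in red in 9 of 9 members, with a median of 0.82. Among them were Rmrp (0.93), the RNA of the ribonuclease that processes ribosomal RNA, and Rpph1 (0.33). Rn45s, by far the most abundant of them, differed by only 0.097 and Scarna6 by 0.060. Histone genes are a family of near-identical copies, so their reads can be divided among members in ways the counting does not show.

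Genes of ribosomal proteins and of the mitochondrial respiratory chain were higher in red by smaller amounts. For ribosomal proteins 32 of 35 members were higher in red, with a median of 0.25 and an adjusted p = 5.79e-05 by camera, and an adjusted p = 0.479 with an estimated correlation. Rps19 (0.68 ± 0.26), Rpl18 (0.50 ± 0.22), Rps18 (0.44 ± 0.20) and Rps11 (0.46 ± 0.20) had the smallest p, and 0 members passed over the list alone in edgeR. For oxidative phosphorylation 27 of 35 members were higher in red, with a median of 0.30 and an adjusted p = 0.00980 by camera, and an adjusted p = 0.277 with an estimated correlation. Its leading members were Cox6b1 (1.25 ± 0.51), Ndufb8 (0.88 ± 0.37), Atp5d (0.73 ± 0.31) and Sdhb (0.57 ± 0.27), and 0 passed over the list alone. That list lost its call without yellow 1 (adjusted p = 0.0871) or yellow 3 (adjusted p = 0.0596).

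Imprinted genes, which are expressed from a single parental allele, were higher in yellow in 8 of 8 tested members. Their median was -0.87 and their adjusted p = 0.000323 by camera, against an adjusted p = 0.277 with an estimated correlation. Kcnq1ot1, a long RNA that silences its neighbours, differed by -0.89 ± 0.34. Grb10, a growth factor receptor adaptor, stood at 10.5 ± 3.92 CPM in red and 20.7 ± 8.70 in yellow. Ndn (-2.14 ± 0.94) was near the lowest measured levels, at 0.721 CPM in red and 3.28 in yellow, and Ppp1r9a differed by -0.85 ± 0.45. None of the 8 passed over the list alone in edgeR, and 3 had an unadjusted p under 0.05.

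Stem cell identity genes were higher in yellow in 18 of 25 members, with a median of -0.20 and an adjusted p = 0.0222 by camera. With an estimated correlation this list had an adjusted p = 0.388. Vwf alone passed over the list (adjusted p = 0.00224, edgeR), and Sult1a1 (-1.80 ± 0.75) and Nupr1 (-1.05 ± 0.70) followed with Ndn. The call ended without red 1, red 3, yellow 1 or yellow 3, with adjusted p between 0.164 and 0.288. Sex-linked genes were higher in yellow in 5 of 5 members, with a median of -0.22, an adjusted p = 0.0425 by camera and an adjusted p = 0.388 with an estimated correlation. Ddx3x, an X-linked RNA helicase, stood at 25.8 ± 4.78 CPM in red and 45.1 ± 8.73 in yellow and passed over the list alone (adjusted p = 0.0252, edgeR). This call ended without any library but red 2, with adjusted p between 0.0563 and 0.242.

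The other 20 lists tested in cohort 1 did not pass, with adjusted p between 0.0949 and 0.974 by camera. Median log2 differences were 0.25 for the erythroid programme, 0.25 for glycolysis and hypoxia, 0.21 for the myeloid progenitor programme, 0.31 for endothelial markers and -0.12 for the megakaryocyte and platelet programme. Within them Pfkl, a phosphofructokinase of glycolysis, differed by 0.98 ± 0.27 and passed over its list alone (adjusted p = 0.0270, edgeR). The myeloid enzyme Mpo (714 ± 364 against 438 ± 133 CPM) and the receptor Csf3r (44.9 ± 12.2 against 26.0 ± 5.26 CPM) were higher in red without passing. Medians were -0.01 for quiescence, -0.18 for Hox genes, -0.06 for immediate early genes, -0.10 for class II and 0.03 for class I antigen presentation, 0.03 for p53 and 0.08 for the lymphoid programme. They were 0.07 for adhesion, 0.04 for the cell cycle, 0.03 for NF-kB, 0.01 for apoptosis, 0.02 for Polycomb, -0.13 for DNA methylation machinery, 0.06 for interferon and -0.02 for heat shock. For interferon the test leaned to yellow against the sign of the median, and for heat shock the mean (0.05) had the opposite sign to the median and the test. Lists of B cell, T and NK cell, neutrophil, monocyte, mast cell and stromal markers had fewer than 4 tested members in cohort 1 and were not tested.

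The comparison of green with purple cells in cohort 2 asks the same question in another cohort with other colours. Immediate early genes, which respond within minutes to stimuli, were higher in purple. Jun, a subunit of the AP-1 transcription factor, stood at 92.0 ± 17.6 CPM in green and 279 ± 79.9 in purple (mean ± SD, n = 2 each), a log2 difference of -1.60 ± 0.26 (SE). Markers of T and NK cells and of mast cells and basophils were also higher in purple. Erythroid and B cell genes were higher in green, such as Car1, a carbonic anhydrase of early red cells, at 76.6 ± 9.88 CPM in green and 30.5 ± 0.413 in purple. None of the 11 lists called by camera stayed called with an estimated correlation between genes, with an adjusted p = 0.367 to 0.551 with an estimated correlation.

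No single gene passed the threshold between green and purple either. Of 11653 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 612 at an unadjusted p under 0.05 (222 higher in green, 390 in purple). DESeq2 called 36, of which 5 were higher in green and 31 in purple, with 524 at an unadjusted p under 0.05. The 10 genes of smallest p all had an adjusted p = 0.795 in edgeR. Of these Podxl, a sialomucin, stood at 29.2 ± 2.11 CPM in green and 6.61 ± 0.697 in purple, and Car1 was the other gene higher in green. Cox6a1, a subunit of cytochrome c oxidase, stood at 176 ± 21.9 and 410 ± 47.3. Ccl5, a chemokine of T and NK cells, stood at 15.8 ± 1.52 and 46.2 ± 2.15, and Klra7, an NK cell receptor of a multigene family, at 12.5 ± 0.210 and 58.5 ± 23.4. The remaining genes were Jun, 2410006H16Rik (-1.10 ± 0.18), Pdap1 (-0.95 ± 0.16), Rps23 (-0.72 ± 0.12) and Apoe (-1.38 ± 0.24). The purple pair differed by a chi-square of 35.1 per degree of freedom against 6.61 for the green pair, and purple 2 had reads in 10994 genes against 14005 to 14381 in the others. Without purple 2 the count of called genes was 272 and without purple 1 it was 6665, in fits that assume the lone purple library to vary like the green ones.

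**Figure D2:**
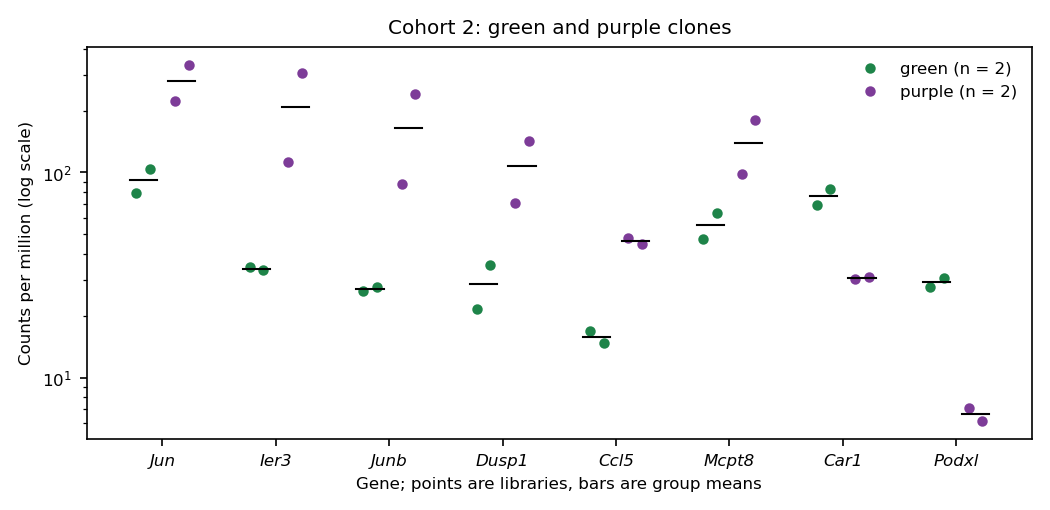
CPM (log axis) of 8 genes in the 2 green and 2 purple libraries of cohort 2, with points for libraries and bars for group means. Jun averaged 92.0 in green and 279 in purple, and Car1 averaged 76.6 in green and 30.5 in purple.

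Immediate early genes made the strongest list of cohort 2. Of 22 members 21 were higher in purple, with a median of -2.0 and an adjusted p = 9.58e-30 by camera in limma. With an estimated correlation the list had an adjusted p = 0.367. Adjusted over the list alone 17 members passed in edgeR and over all genes 0, among the 17 Jun, Ier3 (34.0 ± 1.01 against 209 ± 136 CPM), Junb (27.2 ± 0.835 against 165 ± 109) and the phosphatase gene Dusp1 (28.5 ± 9.86 against 107 ± 50.7). The median member lay 1.18 above the green mean in purple 1 and 2.64 above it in purple 2. NF-kB and inflammatory genes were higher in purple in 26 of 33 members, with a median of -1.04, an adjusted p = 6.89e-16 by camera and an adjusted p = 0.367 with an estimated correlation. Over the list alone 8 passed, including Ccl5, Ier3 and the chemokines Ccl3 (-2.69 ± 0.55) and Cxcl10 (-2.95 ± 0.64). The quiescence list was higher in purple in 15 of 19 members, with a median of -0.45, an adjusted p = 4.86e-07 by camera and an adjusted p = 0.388 with an estimated correlation. Its leading members Junb, Egr1 (-3.48 ± 0.95) and Btg2 (-2.28 ± 0.67) are also immediate early genes, and Cdkn1a (-1.53 ± 0.38) encodes the cell cycle inhibitor p21. Against the green mean the medians of these lists were 0.33 and 0.18 in purple 1 and 1.44 and 0.65 in purple 2.

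Markers of other blood cells also differed between green and purple. T and NK cell markers were higher in purple in 18 of 19 members, with a median of -1.09, an adjusted p = 5.47e-08 by camera and an adjusted p = 0.367 with an estimated correlation. Over the list alone 4 passed in edgeR: Lck (21.2 ± 1.26 against 61.4 ± 17.3 CPM), Il2rb (22.7 ± 0.768 against 47.0 ± 0.753), Klrb1c (14.9 ± 1.82 against 45.0 ± 14.5) and Tcf7 (5.95 ± 0.422 against 20.0 ± 6.84). Their median lay 0.94 above the green mean in purple 1 and 0.96 above it in purple 2. Mast cell and basophil markers were higher in purple in 9 of 10 members, with a median of -0.87, an adjusted p = 7.93e-10 by camera and an adjusted p = 0.367 with an estimated correlation. Over that list alone 6 passed, led by the proteases Prss34 (67.8 ± 5.89 against 143 ± 47.3 CPM) and Mcpt8 (-1.33 ± 0.34), with Fcer1a (-1.06 ± 0.28) and Cpa3 (-0.75 ± 0.21). B cell and plasma cell markers were higher in green in 11 of 12 members, with a median of 1.06, an adjusted p = 5.45e-05 by camera and an adjusted p = 0.367 with an estimated correlation. Igj stood at 86.0 ± 15.6 CPM in green and 43.7 ± 9.01 in purple and Cd19 at 11.1 ± 1.48 and 2.83 ± 1.10, while Ebf1 and Cd79a were below 5 CPM in both colours.

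Red cell and proliferation genes were higher in green. For the erythroid programme 15 of 18 members were higher in green, with a median of 0.49, an adjusted p = 1.48e-05 by camera and an adjusted p = 0.367 with an estimated correlation. It was the only list called by fry (adjusted p = 0.0282), and Car1 passed over the list alone (adjusted p = 0.0160, edgeR). Ermap (1.5 ± 0.40), the transferrin receptor gene Tfrc (0.54 ± 0.15) and Car2 (0.42 ± 0.13) followed. For the cell cycle 29 of 35 members were higher in green, with a median of 0.23, an adjusted p = 0.00180 by camera and an adjusted p = 0.367 with an estimated correlation. Its leading members were Tpx2 (0.45 ± 0.14), Mki67 (0.34 ± 0.13), E2f1 (-0.42 ± 0.17) and Cdk1 (0.43 ± 0.18), and its call ended without purple 1 (adjusted p = 0.0595).

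Stress and antigen presentation genes were higher in purple by smaller amounts. Heat shock and unfolded protein genes were higher in purple in 13 of 17 members, with a median of -0.20, an adjusted p = 0.00214 by camera and an adjusted p = 0.551 with an estimated correlation. Dnajb1 (75.4 ± 3.63 against 186 ± 100 CPM), Atf4 (-0.56 ± 0.19), Dnaja1 (-0.42 ± 0.15) and Hspe1 (-0.47 ± 0.17) led them. Class I antigen presentation was higher in purple in 10 of 13 members, led by the peptide transporter gene Tap2 (-0.56 ± 0.16) and H2-Q4 (-0.45 ± 0.13), with a median of -0.23 and an adjusted p = 0.00735 by camera. With an estimated correlation it had an adjusted p = 0.367. Interferon response genes were higher in purple in 25 of 40 members, led by Irf1 (-1.05 ± 0.35) and Oas1a (-0.58 ± 0.21), with a median of -0.13 and an adjusted p = 0.0303 by camera. With an estimated correlation this list had an adjusted p = 0.551. The last pair of lists lost their calls without green 2 (adjusted p = 0.116 and 0.216) or purple 1 (adjusted p = 0.410 and 0.231).

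The other 21 lists tested in cohort 2 did not pass, with adjusted p between 0.0825 and 0.851 by camera. Medians were -0.21 for stem cell identity, where Gata2 stood at 48.1 ± 9.61 CPM in green and 96.0 ± 27.9 in purple, -0.33 for histone genes, -0.03 for ribosomal proteins, -0.07 for oxidative phosphorylation and 0.11 for imprinted genes. They were -0.37 for class II antigen presentation, -0.14 for glycolysis, -0.24 for the megakaryocyte and platelet programme, -0.03 for apoptosis, -0.05 for adhesion, 0.20 for monocyte markers and -0.14 for neutrophil markers. They were -0.05 for p53, 0.14 for sex-linked genes, -0.02 for the lymphoid and the myeloid programme, 0.04 for DNA methylation machinery, 0.02 for Hox genes, 0.16 for endothelial and 0.09 for stromal markers. The Polycomb list had 14 members higher in green and 13 in purple. For the lymphoid, Polycomb, imprinted and stromal lists the median, mean and test differed in sign. Lck, which is also in the lymphoid list, passed over that list alone (adjusted p = 0.0452, edgeR).

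Genes that differed in 1 cohort were not found more often in the other. Among 8117 genes tested in both cohorts, 0 were called in both by edgeR, with 0 called in each. At an unadjusted p under 0.05 there were 394 in cohort 1 and 502 in cohort 2, of which 23 were shared against 24.4 expected (two-sided Fisher exact test over genes, p = 0.914). DESeq2 called 1 and 30 of these genes, with 0 shared. Genes are not independent replicates, and colours do not correspond between cohorts, so no direction was compared.

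Transcripts of the sorting markers and of mature cells were compared across the bulk libraries. Cd48, whose protein is absent from SLAM stem cells, was set against Slamf1, which encodes CD150. It took 57.8 to 97.9% of the reads of both together in cohort 1 and 97.7 to 100.0% in cohort 2. The cohort 1 shares rest on few reads, such as 16 of Cd48 and 4 of Slamf1 in red 1. With counts scaled to the library total outside Rn45s, Lars2 and Rpph1, the stem cell factor Hlf stood at 233 ± 53.8 CPM in cohort 1 (n = 6) and 25.4 ± 2.31 in cohort 2 (n = 4). The granule and neutrophil genes Mpo, Lyz2 and S100a8 stood at 3868 ± 1903, 121 ± 28.6 and 0.326 ± 0.800 in cohort 1 and at 9107 ± 737, 3005 ± 795 and 2178 ± 615 in cohort 2. The cohorts differ in animals and in their Rn45s share, and no test was made between them. Whether the cohort 2 libraries hold only cells of the sort named in the labels was not settled by these reads, which limits every value of green against purple.

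Reporter and sex-linked reads gave a check on identity. In cohort 1 the reads of the row fRFP were 12, 13 and 13 in the red libraries and 2, 1 and 0 in the yellow ones. Reads of the row fYFP were 109, 360 and 47 in red and 531, 161 and 304 in yellow, which overlap. Xist, which silences an X chromosome in female cells, stood at 2070 ± 305 CPM in cohort 1 and 2445 ± 365 in cohort 2, on the same scale as Hlf. Ddx3y, Uty, Kdm5d and Eif2s3y of the Y chromosome had 0 reads in each of the 10 libraries, which allows up to 3 per library. In WGBS the reads per CpG on X were 0.905 to 1.05 times those on autosomes, and on 7033 Y positions 0.197 to 0.315 times.

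DNA methylation was measured in 6 WGBS libraries. Of all reads at CpGs, 82.9% were methylated in red and 82.3% in yellow, with 1 library each. Over CpGs with at least 10 reads the order turned, at 83.5% in red and 84.1% in yellow. In cohort 2 the level was 77.7% ± 0.436 in green and 78.7% ± 0.719 in purple (SD, n = 2 each). The green minus purple difference of -0.983 percentage points had an exact two-sided permutation p of 0.333, which is the smallest this design allows. Tiles with at least 40 CpGs were 17.7 to 24.2% methylated on autosomes and 47.5 to 55.7% on the X chromosome.

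Between green and purple, 79 of 1716947 tiles were called, 25 higher in green and 54 in purple. The median was 52 reads per tile and library, summed over CpGs. The largest difference toward green lay on chromosome 10, 113270001 to 113271000 (mm9), at 79.5% in green and 39.5% in purple over 13 CpGs. The single libraries stood at 84.2 and 75.7% in green and at 28.8 and 50.0% in purple, with 57 to 74 summed reads each. Next came chromosome 11, 104734001 to 104735000 (77.0 against 42.5%), chromosome 3, 41618001 to 41619000 (83.9 against 50.0%), chromosome 10, 39793001 to 39794000 (52.8 against 20.2%), and chromosome 5, 105719001 to 105720000 (74.1 against 43.5%). In the chromosome 11 tile the single libraries lay far apart, at 66.1 and 90.8% in green and at 57.1 and 30.3% in purple. Toward purple the leading tile was chromosome 7, 6148001 to 6149000, at 25.8% in green and 65.7% in purple, with 31 to 65 reads per library. It was followed by chromosome 11, 26300001 to 26301000 (45.7 against 84.8%), chromosome 2, 92039001 to 92040000 (31.3 against 68.0%), chromosome X, 103502001 to 103503000 (64.1 against 96.0%), and chromosome 7, 87178001 to 87179000 (25.5 against 56.0%). By mean level, 0 of the 79 lay at 0 to 20%, 9 at 20 to 40%, 28 at 40 to 60%, 26 at 60 to 80% and 16 at 80 to 100%. Without purple 1 the balance turned, with 66 tiles higher in green and 45 in purple. The other splits of the 4 libraries into pairs called 69 and 73 tiles, and limma on log ratios called 0, with 85187 at an unadjusted p under 0.05 against 95985 in the quasi-binomial model.

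Between red and yellow, 294 of 1741947 tiles differed by at least 40 percentage points, 139 higher in red and 155 in yellow. The balance turned with the limits, with 26 higher in red and 15 in yellow at 40 reads per library. There is no replicate check on this count. Over 1553051 tiles covered in all 6 libraries it was 206, against 133 and 218 between libraries of the same colour in cohort 2 and 144 to 206 between colours of cohort 2. After thinning to 20 reads per tile it was 5112, against 5062 and 5145 within a colour of cohort 2.

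In cohort 3 single cells of 3 clonal clusters were sequenced on 1 plate, which asks how cells vary within and between clusters. Among wells thinned to 1 depth, 75.8% of cluster 2 (165 wells, exact 95% interval 68.5 to 82.1) had a read of Slc4a1, the anion exchanger of red cells, against 45.0% of cluster 3 (180 wells, 37.6 to 52.6) and 38.5% of cluster 1 (13 wells, 13.9 to 68.4). Tfrc was read in 86.7, 52.8 and 61.5% of them. The stem cell gene Hlf was read in 38.5% of cluster 1, 2.42% of cluster 2 and 3.89% of cluster 3, and Kit in 30.8, 11.5 and 8.33%. Cd79a, a chain of the B cell receptor, was read in 15.4, 15.2 and 19.4%. Without thinning Slc4a1 was read in 53.8, 83.9 and 52.1%.

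**Figure D3:**
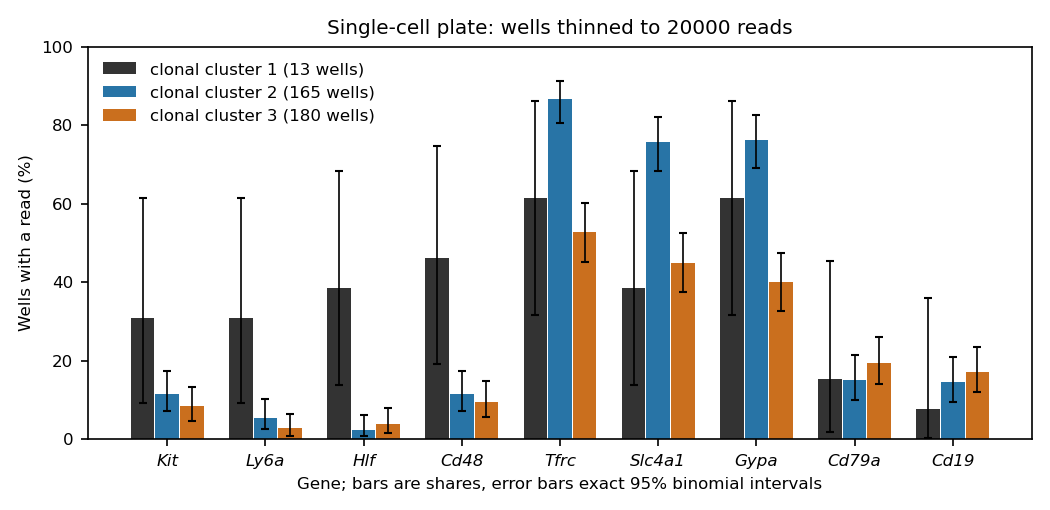
Share of wells with a read (percent) for 9 genes in the 3 clonal clusters of the plate, after thinning each well to 20000 reads; bars are shares and error bars exact 95% binomial intervals. Slc4a1 was read in 75.8% of cluster 2 wells and 45.0% of cluster 3 wells.

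Of 382 wells with a cell 377 were kept, 13, 174 and 190 in clusters 1, 2 and 3, with median reads of 347362, 76752 and 55245. Clusters occupy separate parts of the plate, so cluster and plate position cannot be told apart, and no test was made. By size, 310 genes differed between clusters 2 and 3 by more than 20 percentage points, against 6 to 22 between parts of the plate that hold the same cluster. The largest differences toward cluster 2 were Gypc (66.7 against 25%), H2afx (69.1 against 27.8%), Slc43a1 (72.1 against 31.1%), Abcb10 (74.5 against 34.4%), Smc4 (84.8 against 45.0%), Aqp1 (78.2 against 38.3%), Hmbs, Slc16a1, Rhd and Hemgn. Toward cluster 3 they were Dtwd2, Papss2, Asb13, Gla, Mrc1 (5.45 against 28.3%), Tbc1d8b, Zfp799, Ttn, Gucy1a2 and Vcam1 (10.9 against 33.3%), the last an adhesion molecule of marrow macrophages and stroma.

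Leiden clustering gave 8 expression clusters of 22 to 65 wells. A B cell-like cluster with Cd19, Cd79a, Cd79b, Ms4a1, Ebf1 and Pax5 held 40 wells, 17 from clonal cluster 2 and 23 from cluster 3, which is 10.6% of 377 wells (7.69 to 14.2). The other 7 clusters stayed unnamed. A cluster that held 10 of the 13 wells of clonal cluster 1 had raised Hlf, Mllt3, Ly6a, Mpl, Meis1 and Ifitm1, but its leading genes were Lyz2, Nkg7 and S100a8. A pair of clusters joined cycling genes such as Mki67 and Top2a with the red cell genes Gata1, Klf1, Epor and Tfrc. Beta-s, a beta globin gene, had a read in 100.0% of the 377 wells before thinning and in 89.4% of the thinned wells, with 4 reads in the wells named as empty.

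Genes of smallest p in bulk were not more variable among single cells than random lists of genes read on the plate. Those of cohort 1 were less variable than such lists. Since no gene was called, the 100 genes of smallest p were taken for each cohort, a choice made after the data were seen. The median excess variability of 99 cohort 1 genes lay at the percentile 0.0 of 10000 random lists matched on mean expression, and that of 90 cohort 2 genes at 5.01. Matched on the number of wells instead, the cohort 2 genes lay at 20.6. A choice by smallest p can favour genes with little spread between libraries, so a low percentile may be partly built in. Random lists were drawn from 16298 genes read in at least 10 wells, whether or not those genes had passed the bulk filter. Genes of mature cells missing from the bulk libraries could therefore enter random lists only, which can also lower the percentile. Many wells of the plate carried erythroid or B cell transcripts, so these values do not measure variation among stem cells alone.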

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

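The tests of Kit in wells with Cd79a and of RNAs without a poly(A) tail were set before their results were seen, and the other tests of this part were chosen after. Reads appeared in the 2 wells named as empty, 3927 in P23 and 4943 in P24, over 129 and 208 genes. The shallowest kept well held fewer, 3148, though every kept well had at least 500 detected genes.

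Wells sorted as LKS SLAM carried erythroid or B cell transcripts, although the lineage cocktail holds antibodies against red cells (Ter119) and B cells (B220, CD19). The tables argue against a pool of RNA or reads shared among wells as the source of transcripts at 100 CPM or more. Both Slc4a1 and Cd79a reached it in 16 wells (exact Poisson interval 9.15 to 26.0), below the 27.5 that independence within clonal clusters would give. RNA or reads from a single other well need not bring both genes together, so that count cannot decide on them. In the shallowest kept well, with 3148 reads, a single read already exceeds 100 CPM. Fewer reads also stay open to passing between wells, such as those of Beta-s in each of 377 wells, since the empty wells held 4 Beta-s, 2 Tfrc and 1 Slc4a1 reads. Few reads hiding stem cell transcripts cannot be told apart over 13 wells of cluster 1: after thinning the median number of stem cell identity genes read was 4 there (interval 2 to 9) and 1 in clusters 2 and 3 (1 to 2 in both), and Kit overlapped too, at 30.8% (9.09 to 61.4) against 11.5% (7.08 to 17.4) and 8.33% (4.74 to 13.4), while Hlf went against it, at 38.5% (13.9 to 68.4) against 2.42% (0.664 to 6.09) and 3.89% (1.58 to 7.85). Cells of other types passing the sort remain a candidate explanation. Kit was read in 3.57% of wells with Cd79a at 100 CPM or more (0.435 to 12.3) against 15.9% of the others (12.1 to 20.4), intervals that overlap slightly. For Slc4a1 at that limit it was read in 4.69% (2.17 to 8.71) against 23.8% of the others (17.8 to 30.6). Slc4a1 or Cd79a reached 100 CPM in 232 of 377 wells (61.5%). A difference between clonal clusters was not tested because it coincides with plate position.

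Immediate early genes were higher in both purple libraries. Purple 2 alone does not account for them, since their median in purple 1 also lay 1.18 above the green mean (interval 0.70 to 1.33). The intervals here are over genes, which move together (estimated correlation 0.786), and do not measure the spread between libraries. From purple 1 to purple 2, T and NK cell markers differed by a median of 0.032 (-0.77 to 0.66) and the immediate early genes by 1.54 (1.17 to 2.12). This argues against T and NK cell RNA as the source of that rise, for these single libraries only. For the level of purple 1, T and NK cell RNA cannot be told apart from colour, since the markers lay 0.94 above the green mean there (0.14 to 1.18), an interval that overlaps that of the immediate early genes. Handling before lysis cannot be told apart either, because it is not recorded apart from colour and the median heat shock gene at -0.20 (-0.42 to -0.08) does not decide, and a biological difference between the clonal clusters stays open and untested.

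Of the 19 tested genes of the histone list 18 were higher in red, and the linker histone H1f0 was higher in yellow (-0.70). More cells in S phase would raise the S phase genes too, and their median of 0.090 (-0.088 to 0.32) lay below that of the histone genes (0.51 to 0.75). How far each set would rise with more cells in S phase was not measured, so these values do not exclude it. The intervals are over genes and do not measure the spread between libraries. More capture of RNA without a poly(A) tail in red cannot be told apart from a histone difference: such RNAs had a median of 0.82 with an interval of 0.10 to 1.05, too wide to exclude a shared cause or to require it. The histone list was also called in other splits of the 6 libraries, such as the split that put yellow 2 with red 1 and red 2 (camera, adjusted p = 4.80e-13). A difference between the clonal clusters stays open and untested.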

How the results depend on the processing

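Leaving out Rn45s, Lars2 and Rpph1, the unadjusted overlap, the list tests with all 10 libraries or a lane block, the leave-one-out levels of methylation and the variability of the 100 genes of smallest p were added after the data had been seen. For each value below that moved, the cause was not tested unless stated.

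Genes called between red and yellow (0 in edgeR) were 5 with no filter, 1 at a minimum of 5 CPM, 1 without Rn45s, Lars2 and Rpph1, 4 with DESeq2, and 0 to 7 when 1 library was left out (7 without red 3). Lists called there (6) were 0 with an estimated correlation, 0 with fry, and 3 to 9 without 1 library (3 without yellow 3). With no filter 5 lists were called and the stem cell identity and sex-linked lists lost their calls (adjusted p = 0.0646 and 0.0629). With all 10 libraries in 1 fit the stem cell identity list lost its call (adjusted p = 0.177), as did the interferon list in cohort 2 (adjusted p = 0.0822). Between green and purple (0 genes) there was 1 with all 10 libraries in the fit, 36 with DESeq2, and 0 to 6665 without 1 library (6665 without purple 1, 272 without purple 2, where the lone purple library is assumed to vary like the green ones). Lists there (11) were 0 with an estimated correlation, 1 with fry and 10 to 16 without 1 library. The overlap of calls (0) was 23 genes at an unadjusted p under 0.05. The histone, ribosomal and imprinted lists of cohort 1 and the immediate early, NF-kB, mast cell, T and NK cell, quiescence, erythroid, B cell and heat shock lists of cohort 2 kept their calls whichever library was left out.

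Tiles called between green and purple (79) were 159 at a minimum difference of 10 percentage points and 10 at 30, 38 at 40 reads, 21 in 2 kb tiles, 0 in 500 bp tiles, 0 with limma, and 86 to 132 without 1 library (132 without green 1 or purple 2). Those higher in green and in purple (25 and 54) were 66 and 45 without purple 1. Tiles past the size limit between red and yellow (294, 139 higher in red and 155 in yellow) were 1379 at 10 reads (519 and 860) and 41 at 40 (26 and 15), 3254 at 30 percentage points (1613 and 1641) and 34 at 50 (18 and 16), and 735 in 500 bp tiles (389 and 346); looser limits admit more tiles by construction. The red minus yellow level (0.69 percentage points) was -0.58 over CpGs with at least 10 reads, 1.84 with at least 5, 0.39 with at least 5 in all 6 libraries and 0.70 on autosomes. The red library has 4.25 reads per CpG and the yellow 9.20, so limits on reads keep different CpGs in each. The green minus purple level (-0.98) lay between -1.49 and -0.47 without 1 library. The percentile of cohort 1 genes in single-cell variability (0.0) was 0.12 in thinned wells, and that of cohort 2 genes (5.01) was 5.44 in wells with at least 1000 genes, 2.34 in thinned wells and 20.59 when matched on wells.

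Named genes kept their direction and side in 1395 of 1423 fits in cohort 1 and 1206 of 1376 in cohort 2, and gained a call in 16 and 163. The sign turned when 1 library was left out for the following genes, given with their lowest and highest log2 values over those fits. In cohort 1 these were H2-Ab1 (-0.019 to 0.60, without red 3), Cd74 (-0.33 to 0.015, red 2), Psmb10 (-0.12 to 0.60, red 1), Elane (-0.52 to 1.58, red 3), Runx2 (-0.48 to 0.019, red 3 and yellow 3), Dnmt3a (-0.77 to 0.34, yellow 2), Meis1 (-0.30 to 0.0040, red 1), Kdm5c (-0.41 to 0.034, red 1) and Egfl7 (-0.64 to 0.98, red 1 and yellow 2). In cohort 2 they were Vwf (-1.81 to 0.11, without purple 2), Tet1 (-0.050 to 1.19, purple 2), Xist (-0.029 to 0.35, purple 1), Ddx3x (-0.26 to 0.10, purple 2), Camp (-1.03 to 0.024, green 2), Padi4 (-0.75 to 0.019, purple 2) and Pdgfrb (-0.79 to 0.16, purple 1).

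With the replicate number as a replicate block, 0 genes were called in either cohort by edgeR (409 at an unadjusted p under 0.05 in cohort 1), 6 and 11 lists stayed called, limma called 0 tiles, and Egfl7 turned to 0.078 in cohort 1. Deviations of same-numbered libraries correlated at -0.040, -0.000063 and 0.015 in cohort 1 and -0.011 in cohort 2. Red 1 correlated best with yellow 3 (0.021, against 0.019 with yellow 2). With 2 libraries per colour the deviations mirror each other, so every cohort 2 pair had 0.011 or -0.011. These values show no pairing by number, but they cannot show that same-numbered libraries share no animal or batch. A lane block left 0 genes and 6 lists called. Alternatives for promoter methylation were not run, since no mm9 annotation was used here.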

Other observations

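The tests on splits of the 6 libraries were chosen after the results had been seen, as were the genes named in the next paragraph.

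Beyond the lists, the 36 genes called by DESeq2 between green and purple held Trib1 (17.8 against 177 CPM, log2 green over purple -3.31), Cd69 (44.8 against 213) and the nuclear RNA Malat1 (log2 -1.09), higher in purple. Toward green they held F13a1, which encodes a coagulation factor of monocytes and megakaryocytes (934 against 630 CPM). In edgeR each of these had an adjusted p above 0.05.

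Methylation differed more between cohorts than within them. Beyond the sampling noise of counts taken as independent, the SD of the difference between libraries over 1553051 tiles was 5.27 to 5.70 percentage points between cohorts. It was 3.36 between red and yellow, 3.07 to 3.28 between green and purple libraries, and 3.14 and 3.23 between libraries of the same colour. Cohort coincides with animals and colours, and these were not separated.

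The 6 libraries of cohort 1 can be split into 3 and 3 in 10 ways, so no share of splits can lie under 0.05. The real split gave 0 called genes and the highest other split 0, so 10 of the 10 splits gave as many. It gave 432 genes at an unadjusted p under 0.05, and the highest other split also 432, so 2 of 10 gave as many. It gave 6 called lists, and the highest other split 6, so 2 of 10 gave as many. In cohort 2 the other splits of the 4 libraries called 6 and 5 lists against 11.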
